A study of Rattus norvegicus with 46 samples.

How the data were processed

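The series measured gene expression in heart muscle cells (cardiomyocytes) isolated from adult male Wistar rats and kept in culture. Per the labels, the cells were held for 24 h with 1% bovine serum albumin (BSA) alone, the control, or with the same albumin carrying 0.4 mM of 1 of 5 fatty acids. The fatty acids were octanoate (8 carbons), palmitate (16 carbons), stearate (18 carbons), oleate (18 carbons, 1 double bond) and linoleate (18 carbons, 2 double bonds). Group and replicate number were taken from the labels for all 46 arrays, 7 of control and of linoleate and 8 of each other group. The labels do not say whether replicates came from separate animals or separate cultures, so every p-value measures only the spread between these samples, which may be technical.

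Total RNA was extracted, converted to cDNA and labelled with Cy3 for Illumina rat bead arrays, per the labels' protocols. The first deposited table gave the mean bead intensity of 22517 probes on each array, on a linear scale and not normalized between arrays, and a detection p-value of each probe against the negative control beads of its array, per the file headers. The second deposited table held the intensity of the same arrays after processing by the authors. Its column medians lay between 173.2 and 173.9, the ranks within each column were those of the unprocessed array, and a quantile normalization of the unprocessed values differed from it by at most 3.14%. It was therefore read as linear, quantile-normalized and not background-subtracted, and it served as an alternative. Nothing about centring or direction stayed unknown for it.

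The unprocessed intensities were background-corrected, quantile-normalized and put on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3 (offset 16, with the negative control level inferred from the detection p-values). A probe was kept where its detection p was under 0.01 on at least 7 arrays, the size of the smallest group, which left 7312 probes. A kept probe can thus be below detection in a whole group. Where a probe was detected on no array of the dimmer group, the ratio is given as "at least N-fold". It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own level and the lowest level of any detected probe on that array. That lowest level ran from 6.17 to 8.76 on the log2 scale between arrays. No ratio is given where this bound was under 1, or where a few arrays detected the probe but the mean of the dimmer group was below 6.17. A ratio to a group with few arrays detected is partly one to background, so the number detected is given. For 33 probes the signal reached 65000 on at least 1 array, and the brightest signal was 71781, so levels of the brightest genes may be compressed.

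Probes were named through the RefSeq gene table of the rat assembly GRCr8, without versions, with the names in the array table kept otherwise. Of the 22517 probes, 6330 were named by accession, 5190 by the gene number in their name, 4353 by a current symbol, 1404 by a synonym, 5043 kept the older name of the array table and 197 had none. Accession and symbol both found a gene for 3824 probes and disagreed for 38. For a gene with several kept probes, the probe with the highest mean level stood for it.

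The test was limma's linear model (lmFit, eBayes) on log2 intensity over all 46 arrays with 6 group means and no covariate. All groups shared 1 estimate of the spread per probe. Each fatty acid was compared with control, and 5 further contrasts compared fatty acids differing in a named feature: chain length (palmitate against octanoate, stearate against palmitate) and double bonds (oleate against stearate, linoleate against oleate, linoleate against stearate). An F test asked for any difference among the 6 groups. P-values were adjusted by Benjamini-Hochberg within each contrast, and a probe is called where the adjusted p is under 0.05. Values are given as the log2 difference ± its standard error (SE), or as the ratio of geometric means. The precision of a level is limited by the number of arrays. The median 95% interval of a difference from control reached 0.477 on the log2 scale to either side, a factor of 1.39, and 0.492 for linoleate.

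Before the data were examined, 18 lists of genes of cardiac metabolism, stress and contraction and 6 lists of markers of other cell types were fixed, 518 genes in all, of which 338 were measured. The 19 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 190 tests together. Each test was repeated with the correlation estimated from the data and with fry. Where 2 adjusted p-values follow a list, the second is with the estimated correlation. For each list the number of called members is given over all 7312 probes and, as "over the list alone", with p-values adjusted among its members. In this text a list is said to have risen or fallen only where camera called it.

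The rule for named genes was also fixed beforehand. For each fatty acid against control it takes the 6 largest rises and the 6 largest falls among called probes with a symbol, and for fatty acids against each other 4 and 4. From each list it takes up to 4 members of smallest adjusted p, and 22 preset genes could be given anywhere. No probe of Scd, Ppargc1a or Ppara among the preset genes passed the filter. A gene is named outside this rule only where that is said, and some genes within it are not reported here.

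The procedure was tested on data simulated from the real levels, with 100 probes changed by 1 and 100 by 0.5 on the log2 scale in each fatty acid. Of the larger changes it called 57% (linoleate) to 70% (octanoate) against control among 7312 probes, and of the smaller 11% to 16%. In each, 1 to 6 unchanged probes, the shifted list and 0 of 18 other lists were called. Noise was drawn per probe, so lists of correlated genes went untested.

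Comparisons with control share the same 7 control arrays. Correlations and overlaps between them are therefore given beside 100 simulated sets of unchanged groups with the same controls and beside the values with the controls split into 3 and 4 arrays. Alternatives fixed beforehand were quantile normalization alone, normexp with offset 50, median scaling, the authors' processed values, no filter, detection on all arrays, an adjusted p under 0.01, array weights, the replicate number as a block, only the 2 groups compared in the fit, and each control array left out in turn. Others, added after the data were seen, were array brightness as a covariate, numbers 1 to 4 and 5 to 8 as a block or separately, same-numbered linoleate and oleate arrays as pairs, and leaving out arrays that stood apart. The arrays carry no slide or date in the files used here. No arrays were left out of the main results and no 2 arrays held identical values.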

Results

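Gene expression was measured in cultured adult rat cardiomyocytes after 24 h with albumin alone or with albumin carrying a fatty acid at 0.4 mM, which was stearate, linoleate, palmitate, oleate or octanoate. The design asks how the transcriptional response differs between fatty acids. On average 25.6% ± 3.86 of the probes (SD, n = 7) were detected on the control arrays. The share was 27.4% ± 3.61 with octanoate, 26% ± 3.07 with palmitate, 22.8% ± 6.64 with stearate and 25.7% ± 5.73 with oleate (n = 8 each), and 24.7% ± 3.68 with linoleate (n = 7). Median signals before normalization lay between 134.9 and 230.2 on single arrays. At least 1 group mean differed for 2102 of 7312 probes (limma F test, adjusted p under 0.05).

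The first component of the array levels held 36.5% of their variance and the next 18.1%. Within groups, 4424 probes differed between arrays numbered 1 to 4 and 5 to 8, against at most 109 in 99 random divisions of the same kind. Mustn1, Otud1 and Cd93, which rose with octanoate, averaged log2 11.8 on oleate array 4 and 12 on linoleate array 4, and at most 8.88 and 11 on the other arrays of these groups. Stearate array 4 had Pdk4 at 7.478, near the control mean of 7.104.

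**Figure D1:**
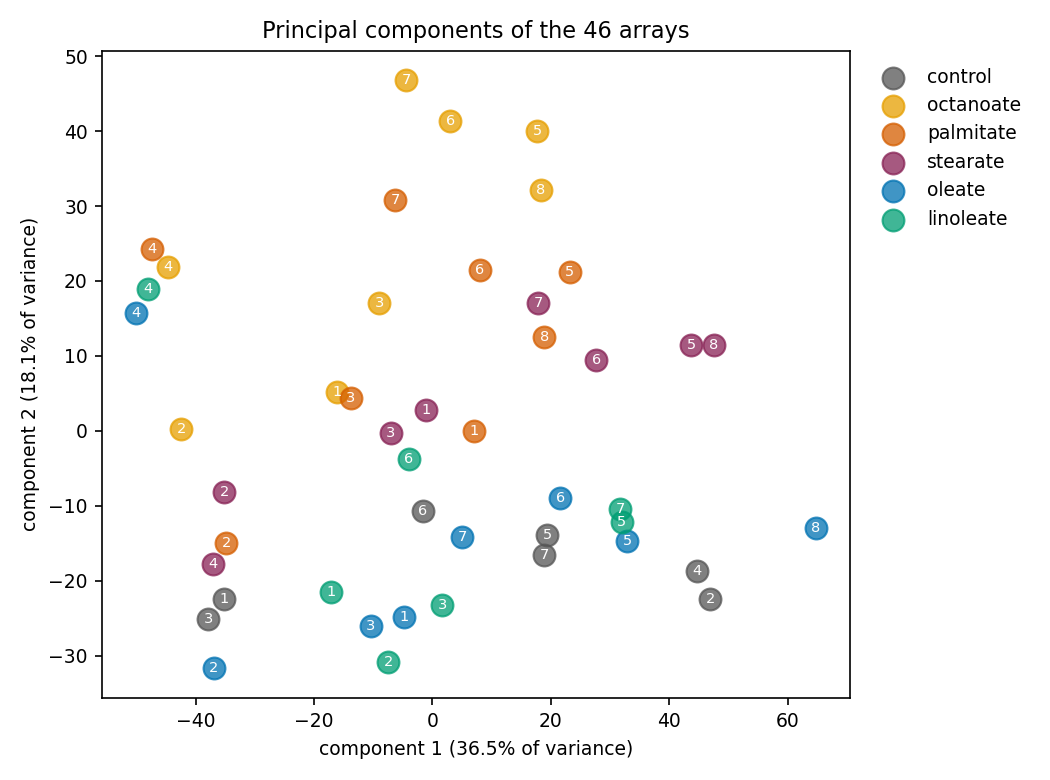
The 46 arrays on the first and second principal components of the log2 intensities of 7312 probes, which hold 36.5% and 18.1% of the variance. Each point is an array, coloured by group and marked with its replicate number; the arrays numbered 4 of octanoate, palmitate, oleate and linoleate lie together at the left.

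**Figure D2:**
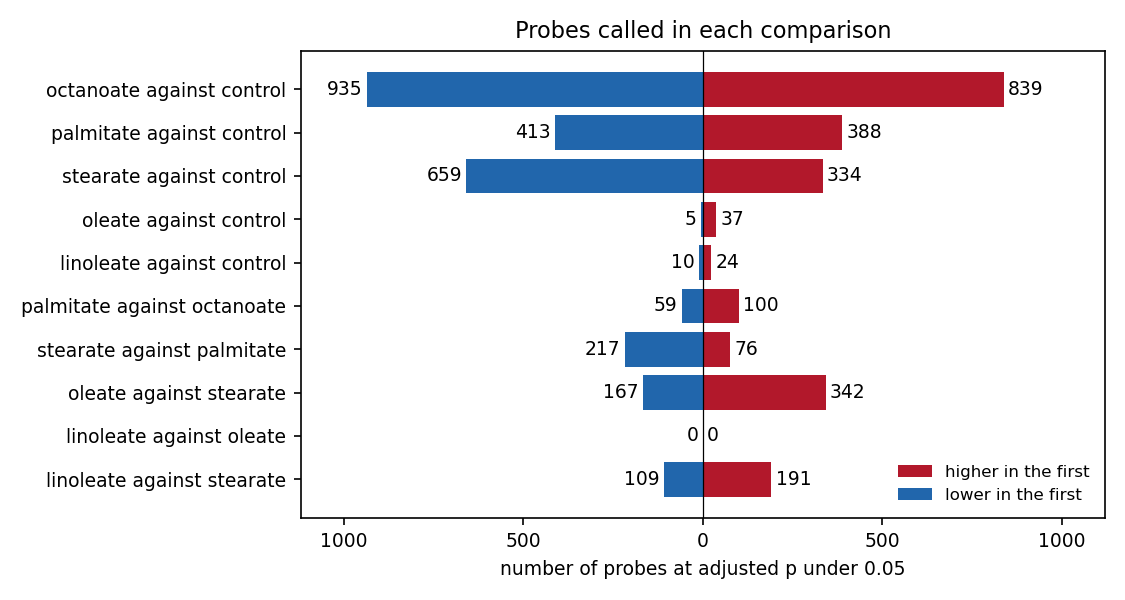
Number of probes called in each comparison at an adjusted p under 0.05, of 7312 tested; bars to the right are probes higher in the group named first and bars to the left those lower.

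Octanoate, the shortest fatty acid, raised genes of endoplasmic reticulum stress and of the amino acid response and lowered genes of fat oxidation, whose lists were not called with an estimated correlation (adjusted p = 0.138 and 0.164). The largest rises were those of Otud1, a deubiquitinase, at 11.5-fold (log2 3.53 ± 0.46, SE, n = 8 and 7, adjusted p = 5.38e-07), and Dnajb9, a chaperone partner of the endoplasmic reticulum, at 8.89-fold (3.15 ± 0.55). They were followed by Mustn1, a nuclear protein of muscle, at 8.80-fold (3.14 ± 0.54), and Cd93, a cell-surface glycoprotein, at 7.59-fold (2.93 ± 0.72). LOC497767 rose 6.21-fold and Atp8b1, a phospholipid flippase, at least 4.08-fold. The largest falls were those of Fam180a, at 8.36-fold lower (log2 -3.06 ± 0.35, adjusted p = 4.82e-08), the secreted ribonuclease Rnase1 (-2.68 ± 0.34), the orphan receptor Gpr22 (-2.34 ± 0.56), the kinase inhibitor Pik3ip1 (-2.22 ± 0.34), the cytoskeletal protein Smtn (-2.17 ± 0.33) and Sspn, a member of the dystrophin complex (-2.02 ± 0.37). Each of these 12 genes lay on the same side of the control mean on 8 of 8 octanoate arrays. On the dimmer side Cd93 was detected on 2 of 7 control arrays, LOC497767 on 1, Dnajb9 on 4 and Otud1 on 6, and among the 8 octanoate arrays Fam180a and Pik3ip1 were detected on 5, Gpr22 on 4 and Smtn on 2.

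Of the 22 measured genes of endoplasmic reticulum stress, 20 rose with octanoate and 0 fell, also 20 over the list alone (camera adjusted p = 2.13e-16). They included the chaperone Hspa5 at 3.41-fold (log2 1.77 ± 0.21), Manf, a secreted protein of the stressed reticulum, at 4.96-fold (2.31 ± 0.34) and the chaperone partner Sdf2l1, detected on 3 of 7 control arrays, at 2.55-fold (1.35 ± 0.18). Of 23 amino acid response genes 16 rose, 20 over the list alone (adjusted p = 4.4e-12). Among them were Asns, which makes asparagine, at least 2.77-fold, Slc3a2, the heavy chain of amino acid transporters, at 4.15-fold (2.05 ± 0.25) and the secreted stress factor Gdf15 at 3.81-fold (1.93 ± 0.31). Of 18 apoptosis and cell death regulators 9 rose and 1 fell, both over all probes and over the list alone (adjusted p = 0.000668), with Birc3, an inhibitor of apoptosis, at 3.91-fold, the receptor Tnfrsf12a at 3.42-fold and Gadd45a, a stress-induced growth arrest gene, at 2.56-fold. These 3 lists were also called with an estimated correlation (adjusted p = 0.0113, 0.0141 and 0.0158). Of 15 fetal and hypertrophy-associated genes 5 rose and 1 fell, also 5 and 1 over the list alone (adjusted p = 0.0388, and 0.271 with an estimated correlation). Ccn1, a matrix protein, rose 4.06-fold and the growth regulator Myc 2.75-fold, and the slow myosin heavy chain Myh7 fell by 1.41 on the log2 scale.

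Of 21 genes of mitochondrial beta-oxidation 9 fell and 0 rose with octanoate, 10 over the list alone (adjusted p = 0.000121, and 0.138 with an estimated correlation). The hydratase Echs1 fell by 0.87 on the log2 scale (SE 0.17), the acylcarnitine transferase Cpt2 by 1.00 and the short-chain dehydrogenase Acads by 1.10. Peroxisomal lipid genes fell at 8 of 15, 9 over the list alone (0.0046, and 0.164), among them the reductases Pecr (log2 -0.98) and Decr2 (adjusted p = 0.000498; detected on 2 of 8 octanoate and 4 of 7 control arrays). Sarcomere and calcium handling genes fell at 8 of 22 with 1 rise, 11 and 1 over the list alone (0.000658, and 0.149). They included Ldb3, a protein of the sarcomere's Z-disc (-1.56 ± 0.30), and phospholamban, Pln, a brake on the calcium pump (-1.62 ± 0.42). Oxidative phosphorylation genes fell at 9 of 38, also 9 over the list alone (0.000405, and 0.42), with the respiratory complex subunits Ndufs3 (-0.96 ± 0.21) and Ndufa2 (-0.57 ± 0.14). Of 21 genes of glucose uptake and glycolysis 5 fell, also 5 over the list alone (0.0289, and 0.446). Among them were Txnip, a repressor of glucose uptake (-1.12 ± 0.17), Pdk2, an inhibitory kinase of pyruvate dehydrogenase (-1.30 ± 0.26), and the glucose transporter Slc2a4 (-0.89 ± 0.25; detected on 2 of 8 octanoate and 6 of 7 control arrays). The PPAR target genes, which respond to fatty acid receptors in the nucleus, were not called as a list (1 rose and 3 fell of 19, also 1 and 3 over the list alone, adjusted p = 0.442). Pdk4, another inhibitory kinase of pyruvate dehydrogenase, differed by 0.13 ± 0.46 (adjusted p = 0.875, higher on 4 of 8 octanoate arrays). It was detected on 7 of these and on 3 of 7 control arrays. The lipid droplet coat protein Plin2 rose 2.88-fold and the lipoprotein lipase Lpl fell by 0.85.

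In all, octanoate changed 1774 probes, 839 higher and 935 lower, and 596 of them by at least 2-fold; median scaling turned this to 1032 higher and 801 lower. Within arrays numbered 1 to 4 the count was 373 and within 5 to 8 it was 1724.

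Palmitate raised PPAR target genes together with endoplasmic reticulum stress, amino acid response and hypertrophy-associated genes. Pik3c2g, a lipid kinase, rose 19.4-fold (log2 4.28 ± 0.39, SE, n = 8 and 7, adjusted p = 9.48e-11), Pdk4 17.5-fold (4.13 ± 0.46), the acyl-CoA thioesterase Acot1 at least 6.63-fold, Otud1 9.92-fold (3.31 ± 0.46), Dnajb9 9.04-fold (3.18 ± 0.55) and Plin2 7.38-fold (2.88 ± 0.44). The largest falls were those of Cdo1, which oxidises cysteine, at 5.35-fold lower (-2.42 ± 0.25, adjusted p = 3.09e-09), Pik3ip1 (-2.03 ± 0.34), Gpr22 (-1.82 ± 0.56), Smtn (-1.76 ± 0.33), Rnase1 (-1.72 ± 0.34) and the homeobox gene Rhoxf2b (-1.69 ± 0.26). All 12 lay on the same side of the control mean on 8 of 8 palmitate arrays. Among the 8 palmitate arrays Cdo1 was detected on 4, Pik3ip1 and Gpr22 on 5 and Smtn and Rhoxf2b on 2, and among the 7 control arrays Otud1 and Rhoxf2b were detected on 6, Pik3c2g on 5, Dnajb9 on 4 and Pdk4 on 3.

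Of the 19 measured PPAR target genes 12 rose with palmitate and 0 fell, 14 over the list alone (camera adjusted p = 3.34e-16). Angptl4, a secreted inhibitor of lipoprotein lipase, rose at least 3.95-fold, while its other kept probe differed by log2 0.52. Lipid droplet genes rose at 5 of 14, also 5 over the list alone (0.00037), with the lipases Lipe at 5.67-fold (2.50 ± 0.28) and Pnpla2 at 2.70-fold (1.43 ± 0.25). Endoplasmic reticulum stress genes rose at 15 of 22, 20 over the list alone (4.85e-19). Among them were Hspa5 at 2.57-fold (1.36 ± 0.21), Ppp1r15a, a phosphatase subunit that restores translation, at 3.82-fold (1.93 ± 0.31), Manf at 3.66-fold, the transcription factor Ddit3 at 2.27-fold and the pseudokinase Trib3 at 2.93-fold. Amino acid response genes rose at 16 of 23, 19 over the list alone (6.14e-16), with Slc3a2 at 3.78-fold, Gdf15 at 4.02-fold and Asns at least 1.79-fold. Fetal and hypertrophy-associated genes rose at 7 of 15, 11 over the list alone (4.69e-08), with the natriuretic peptide Nppb at 5.01-fold (2.33 ± 0.48), Myc at 3.83-fold, Ccn1 at 4.33-fold and the calcineurin inhibitor Rcan1 at 2.02-fold. Cell death regulators rose at 4 of 18, 6 over the list alone (0.00231), with Gadd45a at 3.94-fold and its relative Gadd45b at 1.74-fold. Trib3 was detected on 5 of 7 control arrays and Lipe on 2. These 6 lists were also called with an estimated correlation, at adjusted p = 5.49e-05, 0.0141, 0.00611, 0.00463, 0.00109 and 0.032.

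A further 6 lists were called for palmitate only with the preset correlation. Mitochondrial beta-oxidation genes rose at 7 of 21 with 1 fall, 8 and 1 over the list alone (0.00974, and 0.375 with an estimated correlation). They included the electron carrier Etfdh (log2 0.91 ± 0.20), the carnitine carrier Slc25a20 (0.76 ± 0.17) and Cpt1b, the muscle form of the enzyme that commits fatty acids to oxidation (0.65 ± 0.15). Oxidative stress genes rose at 4 of 20, 7 over the list alone (0.000658, and 0.187). Among them were Osgin1, a growth inhibitor induced by oxidants, at 3.69-fold, Gclc, which begins glutathione synthesis and was detected on 5 of 7 control arrays, at 3.62-fold and the haem oxygenase Hmox1 at 3.63-fold. Cholesterol genes fell as a list, with 3 lower and 1 higher of 18, 7 and 1 over the list alone (0.0106, and 0.33). The sterol isomerase Ebp fell by 0.74 on the log2 scale (SE 0.20), and the member called higher was Insig1, which holds back sterol synthesis (1.62 ± 0.55, adjusted p = 0.0462, detected on 5 of 7 control arrays). Interferon response genes fell at 2 of 19, 4 over the list alone (0.0203, and 0.455), with the immunoproteasome subunit Psmb9 at log2 -1.19 ± 0.27. The sarcomere list, with 1 lower of 22 and 0 over the list alone (0.0315, and 0.42), and oxidative phosphorylation, with 0 of 38 either way (0.0427, and 0.69), also lay lower.

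Palmitate changed 801 probes, 388 higher and 413 lower, and 260 by at least 2-fold; median scaling turned this to 484 higher and 350 lower. The count was 67 within numbers 1 to 4 and 516 within 5 to 8. Without any filter on dim probes the adjusted p of Gpr22 was 0.0891, and over the alternatives tried it ran from 0.0022 to 0.328. The call of Insig1 was lost under most alternatives (adjusted p 0.00835 to 0.517), among them without control array 2, 4 or 7 (0.166, 0.162 and 0.0502).

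**Figure D3:**
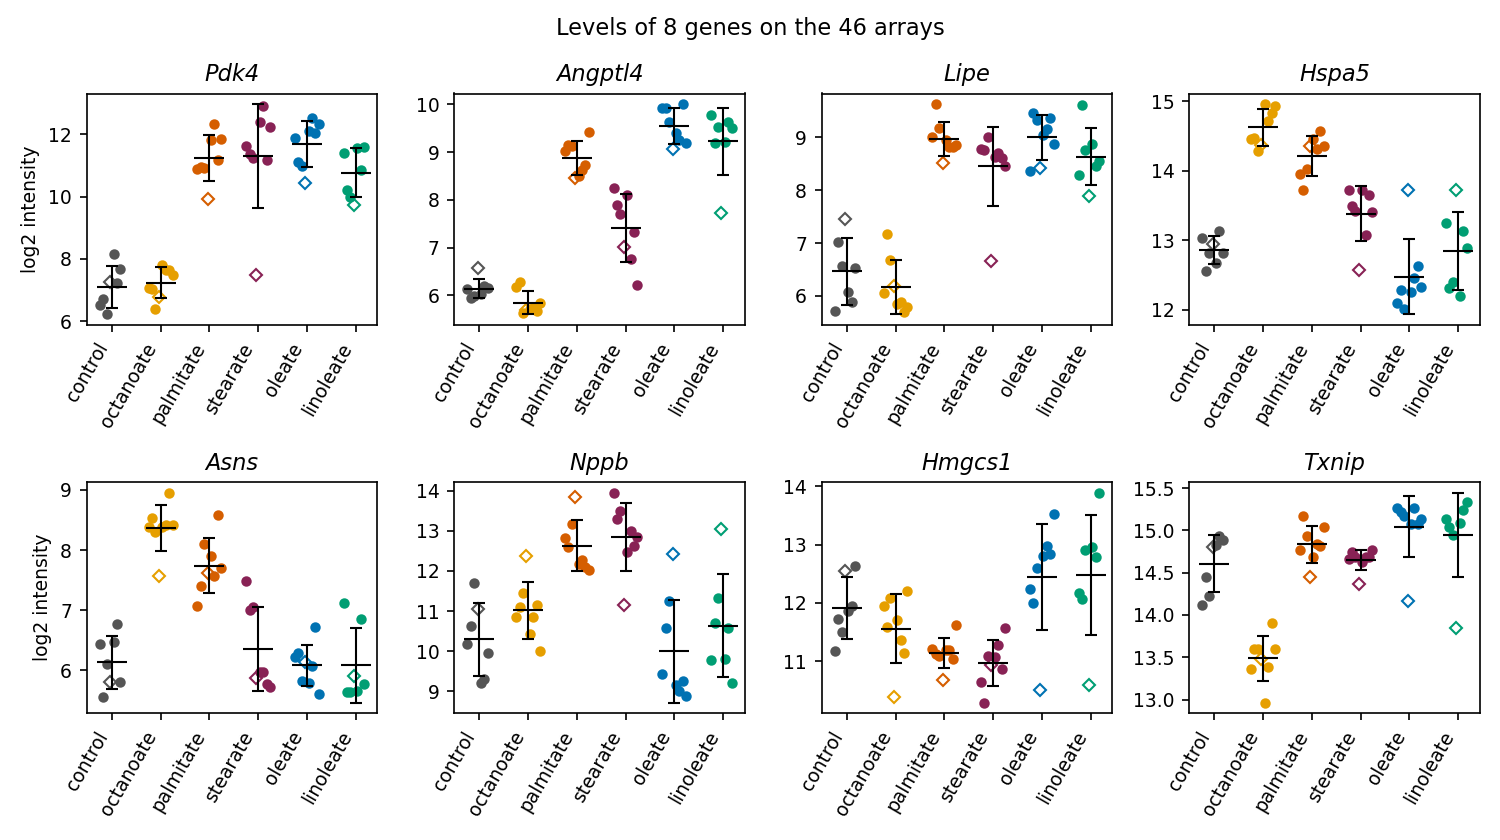
Log2 intensity of 8 genes on the 46 arrays by group; each point is an array, bars show the group mean ± SD, and open diamonds mark the arrays numbered 4. Pdk4 averaged 7.104 in control and 11.23 with palmitate, while Asns averaged 6.135 and 7.744.

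Stearate shared the rise of PPAR target and hypertrophy-associated genes, with 5 called genes of endoplasmic reticulum stress against 15 with palmitate. Pdk4 rose 18.4-fold (log2 4.20 ± 0.46, SE, n = 8 and 7, adjusted p = 3.25e-08), Plin2 7.37-fold (2.88 ± 0.44), Acot1 at least 3.44-fold, LOC501211 7.25-fold (2.86 ± 0.39), Pik3c2g 7.17-fold (2.84 ± 0.39) and Otud1 6.75-fold (2.76 ± 0.46). The largest falls were those of Pik3ip1 at 5.82-fold lower (-2.54 ± 0.34, adjusted p = 1.78e-06), Cdo1 (-2.27 ± 0.25), the pericyte proteoglycan Cspg4 (-2.12 ± 0.32), G0s2, an inhibitor of triglyceride lipase (-2.01 ± 0.65), the chemokine Cx3cl1 (-1.96 ± 0.42) and the lysosomal protein Plbd2 (-1.81 ± 0.26). Each lay on the same side of the control mean on 8 of 8 stearate arrays, except LOC501211 on 7. Of the 8 stearate arrays Acot1 was detected on 7, Plbd2 on 5, Pik3ip1 and Cdo1 on 4 and Cspg4 on 2, and of the 7 control arrays Otud1 was detected on 6, Pik3c2g on 5 and Pdk4 on 3.

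PPAR target genes rose with stearate at 9 of 19, 10 over the list alone (camera adjusted p = 1.9e-10, and 0.000877 with an estimated correlation). Angptl4 rose at least 1.42-fold, being detected on 4 of 8 stearate arrays, and its other kept probe differed by log2 0.43. Fetal and hypertrophy-associated genes rose at 9 of 15, with 10 higher and 1 lower over the list alone (1.06e-08, and 0.000691), with Nppb at 5.88-fold (2.56 ± 0.48), Ccn1 at 3.72-fold, Rcan1 at 1.76-fold and Myc at 2.51-fold. The remaining lists were called only with the preset correlation. Endoplasmic reticulum stress genes rose at 5 of 22, also 5 over the list alone (0.00137, and 0.42). Among them were the stress transcription factor Atf3 at 4.17-fold (2.06 ± 0.42) and Ppp1r15a at 2.09-fold, whereas Trib3 differed by -0.41 ± 0.30 (adjusted p = 0.394). Atf3 and Ppp1r15a were higher on 7 of 8 stearate arrays and Trib3 lower on 6, and Trib3 was detected on 3 of these arrays and on 5 of 7 control arrays. Amino acid response genes rose at 5 of 23 with 1 fall, 7 and 1 over the list alone (0.000512, and 0.284), with Slc3a2 at 2.01-fold. Beta-oxidation genes rose at 4 of 21, 5 over the list alone (1.73e-05, and 0.089), with the isomerase Eci2 at 2.31-fold and Etfdh at 1.77-fold. Lipid droplet genes rose at 3 of 14 with 1 fall, 5 and 2 over the list alone (0.0192, and 0.123), with Lipe, detected on 7 of 8 stearate and 2 of 7 control arrays, at 3.96-fold and Pnpla2 at 2.35-fold. Cell death regulators rose at 5 of 18, with 6 higher and 1 lower over the list alone (0.0224, and 0.123), with Gadd45a at 3.76-fold and Gadd45b at 2.46-fold. Cholesterol genes fell at 3 of 18, 7 over the list alone (0.00636, and 0.289). Oxidative phosphorylation lay higher with 1 called of 38 and 0 over the list alone (0.00636, and 0.556). The chemokine Ccl20, detected on 5 of 7 control arrays, rose 3.99-fold (SE 0.48 on the log2 scale).

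Stearate changed 993 probes, 334 higher and 659 lower, and 261 by at least 2-fold. Median scaling in place of quantiles gave 428 higher and 354 lower and moved the median of all probes from -0.05 to 0.15 on the log2 scale. The count was 94 within numbers 1 to 4 and 1783 within 5 to 8. Stearate arrays 5 to 8, which enter every comparison with stearate, were dim, with a 95th percentile signal of 664 to 915 and 13.7% to 20.6% of probes detected (1584 to 3125 and 25.3% to 32.1% for 1 to 4). With array brightness in the fit 1285 probes were called, 692 of them among the 993. The call of G0s2 was lost without control array 2, 3 or 4 (adjusted p = 0.0635, 0.0573 and 0.0941), without a filter (0.0891) and with array brightness in the fit (0.121), and over alternatives the adjusted p ran from 0.000743 to 0.17.

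Oleate gave a small response, in which genes of 4 lists of fat handling rose. Pdk4 rose 23.9-fold (log2 4.58 ± 0.46, SE, n = 8 and 7, adjusted p = 1.43e-09), Pik3c2g 22.6-fold (SE 0.39 on the log2 scale), Acot1 at least 5.13-fold, Angptl4 at least 6.28-fold, the glycerol channel Aqp7 7.86-fold (2.97 ± 0.23) and the retinol saturase Retsat 6.90-fold (2.79 ± 0.30). The other kept probe of Angptl4 differed by log2 0.91. Of the 5 falls, the largest were those of the iron hormone Hamp (-1.59 ± 0.31, adjusted p = 0.00182), Fam180a (-1.37 ± 0.35, adjusted p = 0.0453) and Cdo1 (-1.32 ± 0.25, adjusted p = 0.00164). The others were the mitochondrial carrier Slc25a29 (-0.91 ± 0.20, adjusted p = 0.0107) and 1 of the probes of the glucagon receptor Gcgr (-0.88 ± 0.21, adjusted p = 0.0258). Gcgr was named after its value was seen, and its brighter probe missed the threshold (-0.90, adjusted p = 0.0743), though not with the replicate number or the number sets as a block (0.0039 and 0.0388; 0.0039 to 0.593 over alternatives). All of these except Gcgr, for which this was not counted, lay on the same side of the control mean on 8 of 8 oleate arrays. Of these arrays Cdo1 was detected on 7 and Slc25a29 on 2, and of the 7 control arrays Retsat was detected on 6, Pik3c2g on 5, Aqp7 on 4 and Pdk4 on 3.

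PPAR target genes rose with oleate at 13 of 19, 17 over the list alone (camera adjusted p = 2.44e-79), with the mitochondrial carrier Ucp3 at least 2.17-fold and the lipid droplet protein Plin5 at least 1.49-fold. Of the 8 oleate arrays Ucp3 was detected on 7 and Plin5 on 6. Beta-oxidation genes rose at 7 of 21, with 11 higher and 1 lower over the list alone (3.85e-24), among them Slc25a20 at 2.36-fold (1.24 ± 0.17), Cpt1b at 1.93-fold (0.95 ± 0.15) and the isomerase Ech1 at 2.65-fold (1.41 ± 0.23). Lipid droplet genes rose at 5 of 14, 7 over the list alone (2.71e-21), with Lipe, detected on 2 of 7 control arrays, at 5.79-fold (2.53 ± 0.28) and Pnpla2 at 3.67-fold (1.88 ± 0.25). Peroxisomal lipid genes rose at 2 of 15, 4 over the list alone (1.63e-05). These 4 lists were also called with an estimated correlation, at adjusted p = 1.77e-13, 6.33e-05, 1.66e-08 and 0.0248. Cholesterol genes rose as a list with 0 of 18 called, also 0 over the list alone (2.64e-05, and 0.0684 with an estimated correlation). Idi1, an isomerase of the pathway, differed by 1.00 ± 0.34 (adjusted p = 0.381, but 0.0245 with array weights; detected on 5 of 7 control arrays). A further 5 lists lay lower with 0 members called over all probes and 0 over the list alone, except 1 of the amino acid response. These were interferon response (0.00616, and 0.375), sarcomere (0.0141, and 0.35), inflammatory mediators (0.0302, and 0.432), endoplasmic reticulum stress (0.0447, and 0.665) and amino acid response (0.0447, and 0.592). Nppb differed by -0.30 ± 0.48 and Ddit3 by -0.63 ± 0.30 (adjusted p = 1.0 for both; lower on 5 and 7 of 8 oleate arrays).

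Oleate changed 42 probes, 37 higher and 5 lower, and 33 by at least 2-fold; 314 passed an unadjusted p of 0.05 where 366 are expected by chance. Within numbers 1 to 4 the count was 23 and within 5 to 8 it was 32. Fam180a lost its call without control array 2, 4, 5, 6 or 7 (adjusted p = 0.187, 0.157, 0.129, 0.0601 and 0.103; 0.00164 to 0.684 over alternatives) and Slc25a29 without control array 2 (0.0506) or with median scaling (0.101; 0.000462 to 0.564). With only the oleate and control arrays in the fit, the adjusted p of Cdo1 was 0.0917 (0.000295 to 0.689).

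Linoleate gave a response of 34 probes, where oleate gave 42, and its 6 largest rises were in the 6 genes with the largest rises under oleate. Pik3c2g rose 14.1-fold (log2 3.82 ± 0.40, SE, n = 7 and 7, adjusted p = 6.47e-09), Pdk4 12.7-fold (3.66 ± 0.48), Angptl4 at least 5.0-fold, Acot1 at least 3.15-fold, Retsat 6.03-fold (2.59 ± 0.31) and Aqp7 5.81-fold (2.54 ± 0.24). The other kept probe of Angptl4 differed by log2 0.67. The largest falls were those of Fam180a (-1.66 ± 0.36, adjusted p = 0.0101), Rnase1 (-1.42 ± 0.35, adjusted p = 0.0459), Cdo1 (-1.17 ± 0.26, adjusted p = 0.015), Gchfr, which inhibits tetrahydrobiopterin synthesis (-1.09 ± 0.22, adjusted p = 0.00389), Slc25a29 (-0.98 ± 0.21, adjusted p = 0.00733) and the protein kinase PRKCQ (-0.94 ± 0.22, adjusted p = 0.0293). All 12 lay on the same side of the control mean on 7 of 7 linoleate arrays. Of these arrays Slc25a29 was detected on 2 and Gchfr and PRKCQ on 1, and of the 7 control arrays Retsat and PRKCQ were detected on 6, Pik3c2g on 5, Aqp7 on 4 and Pdk4 on 3.

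PPAR target genes rose with linoleate at 9 of 19, 15 over the list alone (camera adjusted p = 2.5e-41). Beta-oxidation genes rose at 5 of 21, 8 over the list alone (5.59e-13), with Cpt1b at 2.02-fold (SE 0.15 on the log2 scale), Slc25a20 at 1.99-fold (0.99 ± 0.18) and Etfdh at 2.10-fold (1.07 ± 0.21). Lipid droplet genes rose at 4 of 14, 6 over the list alone (3.5e-10), with Lipe, detected on 2 of 7 control arrays, at 4.49-fold (2.17 ± 0.28) and Pnpla2 at 2.84-fold (1.51 ± 0.26). These 3 lists were also called with an estimated correlation, at adjusted p = 1.96e-09, 0.00369 and 5.54e-05. Cholesterol genes rose as a list with 0 of 18 called, 1 over the list alone (3.55e-05, and 0.0738 with an estimated correlation), Idi1 differing by 1.29 ± 0.35 (adjusted p = 0.111; detected on 5 of 7 control arrays). Idi1 was called with the replicate block (0.0216), array weights (0.0141), array brightness in the fit (0.0301) and without control array 1 or 3 (0.044 and 0.0172; 0.0141 to 0.999 over alternatives). Peroxisomal lipid genes rose with 0 of 15 called, 2 over the list alone (0.00974, and 0.224). The endoplasmic reticulum stress and amino acid response lists were not called (adjusted p = 0.904 and 0.45).

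Linoleate changed 34 probes, 24 higher and 10 lower, and 24 by at least 2-fold; median scaling gave 25 higher and 4 lower. Within numbers 1 to 4 the count was 10 and within 5 to 8 it was 14. Rnase1 lost its call without control array 2, 3, 4, 6 or 7 (adjusted p = 0.174, 0.0678, 0.191, 0.0909 and 0.0741), PRKCQ without 2, 4, 5, 6 or 7 (0.054, 0.073, 0.109, 0.0643 and 0.0829) and Cdo1 without 4 (0.0847). Median scaling ended the calls of Gchfr (0.096), Slc25a29 (0.348) and PRKCQ (0.692), and a fit of only these 2 groups that of Slc25a20 (0.122). Over alternatives the adjusted p ran from 0.00377 to 0.751 for Rnase1, 0.00432 to 0.692 for PRKCQ, 0.00346 to 0.945 for Cdo1, 0.00146 to 0.284 for Gchfr, 0.00133 to 0.841 for Slc25a29 and 2.44e-07 to 0.471 for Slc25a20.

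Called probes overlapped between fatty acids. Lpcat3, which remodels phospholipids, and Por, the electron donor of cytochrome P450 enzymes, were higher with all 5 fatty acids, and Cdo1 was lower with all 5. With palmitate, stearate, oleate and linoleate 17 probes were higher in common, among them those of Acot1, Angptl4, Aqp7, Etfdh, Lipe, Pdk4, Pik3c2g, Pnpla2, Retsat and Slc25a20, and 2 were lower, Cdo1 and Slc25a29. Octanoate, palmitate and stearate shared 92 higher and 185 lower. Lpcat3 and Por were named after their overlap was seen. Without control array 1, 3, 5 or 6 the call of Por was lost with oleate (adjusted p = 0.0937, 0.0876, 0.0556 and 0.0601; 0.000906 to 0.418 over alternatives) and with linoleate (0.141, 0.128, 0.101 and 0.0968; 0.00424 to 0.503). The call of Lpcat3 with octanoate was lost without control array 2 or 7 (0.0762 and 0.0505; 0.00612 to 0.617), and that of Slc25a20 with stearate without 1, 3 or 7 (0.079, 0.0516 and 0.0525; 0.00114 to 0.341). Median scaling ended the calls of Slc25a29 with stearate, oleate and linoleate (0.263, 0.101 and 0.348; 0.000462 to 0.841 over alternatives). A fit of only 2 groups ended those of Lpcat3 with oleate (0.0917; 3.13e-06 to 0.652) and Por with stearate (0.0675; 3.66e-05 to 0.388).

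Across the 7312 probes the log2 differences from the shared controls correlated most between oleate and linoleate (r = 0.852) and between octanoate and palmitate (0.819). The other pairs gave 0.697 for palmitate and stearate, 0.675 for palmitate and linoleate, 0.609 for palmitate and oleate, 0.589 for stearate and linoleate, 0.53 for octanoate and stearate, 0.501 for stearate and oleate, 0.479 for octanoate and linoleate and 0.355 for octanoate and oleate. Probes are not independent replicates, so no p-value is attached. Unchanged groups simulated against the same controls, not balanced by number set, gave means of 0.495 to 0.545 and reached 0.9 to 0.949. With the controls split into 3 and 4 arrays, each set serving 1 side, the median correlation over 35 splits ran from 0.124 for octanoate and oleate to 0.627 for octanoate and palmitate. The order changed, as oleate and linoleate (0.354) came after palmitate and stearate (0.488), palmitate and linoleate (0.388) and octanoate and stearate (0.368). The covariance was 0.234 for octanoate and palmitate, where unchanged groups gave 0.04. For the other 9 pairs it ran from 0.0569 to 0.163 (0.0719 for oleate and linoleate), where unchanged groups gave 0.0365 to 0.0428. Octanoate and palmitate had 292 higher and 344 lower calls in common, where independent lists of these lengths would share 44.5 and 52.8 and unchanged groups shared 3.01 and 2.26 on average. Palmitate and stearate shared 130 and 220 (independent lists 17.7 and 37.2) and oleate and linoleate 23 and 3 (0.121 and 0.00684), while unchanged groups shared 0 in both cases. With the controls split the median overlaps were 97 and 84, 41.5 and 38.5, and 11.5 and 0 for these 3 pairs. Part of such overlaps may come from the shared controls.

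**Figure D4:**
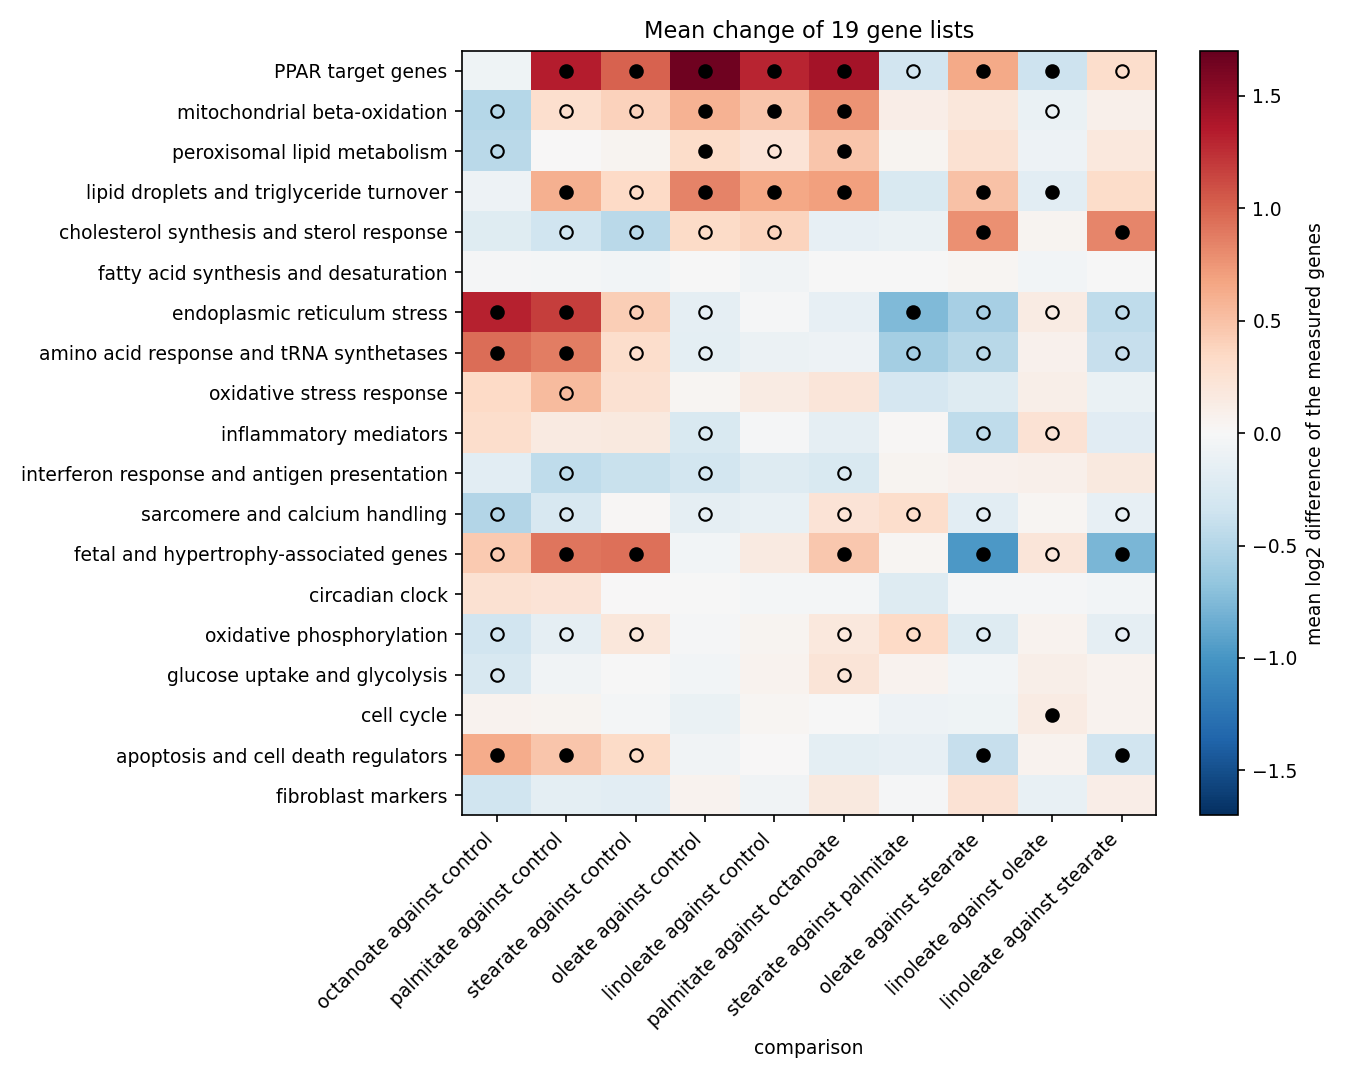
Mean log2 difference of the measured genes of the 19 tested lists in the 10 comparisons, on a colour scale from lower (blue) to higher (red). Filled circles mark lists called by camera with both the preset and the estimated correlation (35 tests) and open circles those called with the preset correlation only (49 tests).

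Palmitate and octanoate differ in chain length and were given at the same dose and time. PPAR target genes were higher with palmitate, whereas the endoplasmic reticulum stress and amino acid response lists were not called as different (camera adjusted p = 0.0702 and 0.476). Pik3c2g was 28.5-fold higher with palmitate (log2 4.83, 95% interval 4.07 to 5.59, n = 8 and 8, adjusted p = 4.55e-13), Pdk4 16-fold (interval 3.10 to 4.90), and Acot1 8.64-fold (3.11, 2.34 to 3.88). Angptl4 was called too (adjusted p = 4.55e-13), but averaged 5.843 with octanoate, below the level of any detected probe, so no ratio is given, and its other kept probe differed by 0.55. Octanoate was higher for Vcam1, an adhesion molecule of inflamed vessels (-1.59 ± 0.29), the adaptor Sh2b2 (at least 1.59-fold) and the growth factor Bmp2 (-1.40, -2.09 to -0.70). All 7 lay on the same side of the octanoate mean on 8 of 8 palmitate arrays. Of the 8 octanoate arrays Pik3c2g was detected on 5, Pdk4 on 7, Acot1 on 3 and Angptl4 on 1, and of the palmitate arrays Vcam1 was detected on 2.

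With palmitate against octanoate, PPAR target genes were higher at 12 of 19, 17 over the list alone (camera adjusted p = 2.47e-37), including Mlycd, which degrades malonyl-CoA, at 3.11-fold. Beta-oxidation genes were higher at 10 of 21, 17 over the list alone (8.99e-25), with Cpt1b at 2.10-fold, Ech1 at 3.07-fold and Etfdh at 2.43-fold. Lipid droplet genes were higher at 3 of 14, 7 over the list alone (1.17e-07), with Pnpla2 at 2.54-fold and Lipe (adjusted p = 1.67e-10), which has no ratio, being detected on 1 of 8 octanoate arrays with a mean of 6.165. Peroxisomal lipid genes were higher at 3 of 15, 6 over the list alone (3.34e-07), with the bifunctional enzyme Hsd17b4 at 1.97-fold and the epoxide hydrolase Ephx2 at 1.57-fold. Fetal and hypertrophy-associated genes were higher at 2 of 15, 4 over the list alone (0.000128), with the matrix protein Ccn2 at 2.11-fold and Myh7 at 2.31-fold. Ephx2 and Myh7 were higher on 7 of 8 palmitate arrays. These 5 lists were also called with an estimated correlation, at adjusted p = 5.54e-09, 5.54e-05, 0.000428, 0.00876 and 0.02. With the preset correlation only, oxidative phosphorylation was higher with 0 of 38 called, 0 over the list alone (0.00162, and 0.471 with an estimated correlation), and sarcomere with 1 of 22, 1 over the list alone (0.00551, and 0.275). Glucose uptake and glycolysis was higher with 1 of 21, 1 over the list alone (0.0078, and 0.35), where Txnip was 2.55-fold higher. Interferon response was lower with 0 of 19, 0 over the list alone (0.025, and 0.471). The chaperone partner Sdf2l1 and the stress protein Nupr1 were lower with palmitate (log2 -1.02 ± 0.17 and -1.17 ± 0.26), with Sdf2l1 detected on 6 of 8 palmitate arrays, and Hspa5 differed by -0.41 (interval -0.81 to -0.0018, adjusted p = 0.389).

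Palmitate and octanoate differed at 159 probes, 100 higher and 59 lower with palmitate, 71 of them by at least 2-fold; the count was 16 within numbers 1 to 4 and 282 within 5 to 8. With only these 2 groups in the fit the adjusted p of Bmp2 was 0.121 (0.000415 to 0.976 over alternatives), and without a filter that of Myh7 was 0.0775 (9.51e-05 to 1.0).

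Stearate, longer by 2 carbons, gave lower levels of endoplasmic reticulum stress genes than palmitate. Hamp was 4.99-fold higher with stearate (log2 2.32, 95% interval 1.71 to 2.92, n = 8 and 8, adjusted p = 6.06e-06), LOC501211 3.67-fold (1.87, 1.11 to 2.64), Rhoxf2b 3.22-fold (1.69, 1.19 to 2.18) and LOC501066 2.76-fold (1.46, 0.88 to 2.05). Trib3 was 3.89-fold lower (-1.96, -2.54 to -1.38, adjusted p = 2.65e-05), the chaperone partner Dnajc25 3.01-fold (-1.59, -2.20 to -0.98), Fndc3a 2.94-fold (-1.56, -2.06 to -1.05) and Angptl4 2.78-fold (-1.47, -1.94 to -1.0), although the other kept probe of Angptl4 differed by -0.09. All lay on the same side of the palmitate mean on 8 of 8 stearate arrays, except LOC501211 on 7. Of the 8 stearate arrays Rhoxf2b, Fndc3a and Angptl4 were detected on 4, Trib3 on 3 and Dnajc25 on 2, and of the palmitate arrays Rhoxf2b was detected on 2.

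Endoplasmic reticulum stress genes were lower with stearate than with palmitate at 7 of 22, 15 over the list alone (camera adjusted p = 1.85e-11, and 0.0384 with an estimated correlation). Among them were Syvn1, a ubiquitin ligase of the reticulum (-1.23 ± 0.18), the folding enzyme Pdia3 (-0.82 ± 0.19) and Hspa5 (-0.84 ± 0.20, adjusted p = 0.0103). The remaining lists were called only with the preset correlation. Amino acid response genes were lower at 6 of 23, 10 over the list alone (3.52e-08, and 0.0584). Among them were Asns at -1.39 ± 0.25 and the methionine tRNA synthetase Mars1 at -0.58 ± 0.15. The Asns level was 7.004 to 7.481 on stearate arrays 1 to 3, overlapping the palmitate arrays (7.07 to 8.591), and 5.721 to 5.969 on 4 to 8, of which 5 to 8 were dim. PPAR target genes were lower at 2 of 19, 4 over the list alone (0.0196, and 0.275), though Pdk4 differed by 0.08 (interval -0.83 to 0.98, adjusted p = 0.956; 0.623 without stearate array 4). Oxidative phosphorylation was higher at 2 of 38, 7 over the list alone (6.6e-10, and 0.1). Sarcomere genes were higher at 1 of 22, 4 over the list alone (7.7e-05, and 0.0861), with the ventricular myosin light chain Myl2 at 2.72-fold. Nppb differed by 0.23 (interval -0.70 to 1.16, adjusted p = 0.833; 0.475 without stearate array 4), and both Pdk4 and Nppb were higher on 6 of 8 stearate arrays.

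Stearate and palmitate differed at 293 probes, 76 higher and 217 lower with stearate, 58 of them by at least 2-fold; median scaling gave 128 higher and 151 lower. The count was 1 within numbers 1 to 4 and 1149 within 5 to 8. With median scaling the adjusted p of Hspa5 was 0.0591 (0.000966 to 0.767 over alternatives).

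Oleate differs from stearate by a double bond, and gave higher levels of cholesterol and PPAR target genes and lower levels of hypertrophy-associated genes and cell death regulators. Angptl4 was 4.42-fold higher with oleate (log2 2.14, 95% interval 1.67 to 2.61, n = 8 and 8, adjusted p = 5.23e-08; the other kept probe 0.48), and G0s2 4.06-fold (2.02, 0.76 to 3.28). The phospholipid-remodelling enzyme Lpcat1 was called higher too (adjusted p = 5.3e-07), but averaged 5.944 with stearate, below the level of any detected probe, so no ratio is given. Nppb was 7.22-fold lower (-2.85, -3.78 to -1.92, adjusted p = 4.48e-05), Ccl20 6.79-fold (-2.76, -3.70 to -1.83), Hamp 6.18-fold (-2.63, -3.23 to -2.02) and the kinase Sgk1 5.74-fold (-2.52, -3.22 to -1.82). All lay on the same side of the stearate mean on 8 of 8 oleate arrays. Of the 8 stearate arrays Lpcat1 was detected on 1 and Angptl4 on 4, and of the oleate arrays Lpcat1 and Ccl20 were detected on 7 and Sgk1 on 6.

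Cholesterol genes were higher with oleate than with stearate at 9 of 18, 13 over the list alone (camera adjusted p = 1.06e-08). Among them were the synthase Hmgcs1, at the start of the pathway, at 2.77-fold (1.47 ± 0.32), Acat2, which makes its first intermediate, at 2.14-fold (1.10 ± 0.23) and the desaturase Sc5d at 2.27-fold (1.18 ± 0.25). Of the 8 stearate arrays Acat2 was detected on 7 and Sc5d on 5, and Hmgcs1 and Sc5d were higher on 7 of 8 oleate arrays. PPAR target genes were higher at 6 of 19, with 8 higher and 1 lower over the list alone (5.53e-07), with Cpt1b at 1.67-fold. Lipid droplet genes were higher at 4 of 14, with 6 higher and 1 lower over the list alone (0.00231), with Plin5, detected on 6 of 8 oleate arrays, at least 1.08-fold. Pdk4 differed by 0.37 (interval -0.53 to 1.28, adjusted p = 0.68, higher on 5 of 8 oleate arrays), and by -0.173 without stearate array 4. Fetal and hypertrophy-associated genes were lower at 8 of 15, with 10 lower and 1 higher over the list alone (2.35e-11), with Ccn2 at -1.19 ± 0.19, the immediate early gene Egr1 at -2.08 ± 0.39 and Rcan1 at -0.77 ± 0.16. Cell death regulators were lower at 6 of 18 with 1 higher, 7 and 3 over the list alone (0.002), with Gadd45a at -1.93 ± 0.28 and Gadd45b at -1.36 ± 0.17. These 5 lists were also called with an estimated correlation, at adjusted p = 0.0113, 0.00876, 0.0374, 9.84e-05 and 0.0297. With the preset correlation only, endoplasmic reticulum stress genes were lower at 6 of 22, 10 over the list alone (5.07e-07, and 0.149 with an estimated correlation). Among them were Atf3 at -2.10 ± 0.40, Ddit3 at -1.51 ± 0.29 and Ppp1r15a, lower on 7 of 8 oleate arrays, at -1.47 ± 0.30. Amino acid response genes were lower at 4 of 23, 11 over the list alone (5.32e-08, and 0.0624), with the serine-making phosphatase Psph at -1.08 ± 0.23 and Slc3a2 at -1.02 ± 0.25. Oxidative phosphorylation lay lower with 0 of 38, 0 over the list alone (0.000144, and 0.38). Sarcomere genes were lower at 5 of 22, 7 over the list alone (0.00888, and 0.315), and inflammatory mediators at 1 of 16, 4 over the list alone (0.0315, and 0.435). Atf3 and Gadd45b were detected on 7 of 8 oleate arrays.

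Oleate and stearate differed at 509 probes, 342 higher and 167 lower with oleate, 165 of them by at least 2-fold; median scaling gave 234 higher and 190 lower. The count was 8 within numbers 1 to 4 and 990 within 5 to 8. Without a filter the adjusted p of G0s2 was 0.114 and with array brightness in the fit 0.0692 (0.000251 to 0.165 over alternatives).

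Linoleate, with 1 double bond more than oleate, was not told apart from it at any single probe in the main fit. With limma 0 of 7312 probes were called, the smallest adjusted p was 0.902, and 35 probes passed an unadjusted p of 0.05 where 366 are expected by chance. The median 95% interval of a difference reached 0.477 to either side, so differences up to about 1.39-fold were not excluded for a typical probe. With array weights 1 probe was called. In the unweighted fit Ucp3 was lower with linoleate by -1.0 (95% interval -1.55 to -0.46, n = 7 and 8, adjusted p = 1.0), Plin5 by -0.65 (-1.02 to -0.27, adjusted p = 1.0) and Pdk4 by -0.91 (-1.85 to 0.02, adjusted p = 1.0). Of the 7 linoleate arrays Plin5 was detected on 3 and Ucp3 on 4, and of the 8 oleate arrays Ucp3 on 7 and Plin5 on 6. As lists, PPAR target genes were lower with linoleate (mean -0.35, camera adjusted p = 2.51e-12, and 0.000315 with an estimated correlation), with 0 of 19 called and 3 over the list alone. Lipid droplet genes were lower (mean -0.18, 8.39e-05, and 0.00792), with 0 of 14 called and 1 over the list alone. The 8 measured cell cycle genes were higher (mean 0.14, 0.00425, and 0.0137), with 0 called either way. With the preset correlation only, beta-oxidation was lower (0.00513, and 0.33), and endoplasmic reticulum stress (0.00476, and 0.471), inflammatory mediators (0.00105, and 0.187) and hypertrophy-associated genes (0.00513, and 0.1) were higher, with 0 members called either way in these 4 lists. The count was 0 too within numbers 1 to 4, within 5 to 8, with the replicate block and with same-numbered arrays as 7 pairs, which the labels do not give. As pairs the smallest adjusted p was 0.094 and 260 probes passed an unadjusted 0.05, so the 35 do not show likeness. Pdk4 (-0.818, pairs -1.67 to -0.445), Pik3c2g, Acot1, Aqp7 and Ucp3, picked in part after their values were seen and not called, were lower in every pair. Of the 19 PPAR target genes, which overlap these, 5 were lower and 0 higher in every pair. Over all probes 53 were lower and 34 higher in every pair, where chance gives 57.1 each.

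Linoleate against stearate, a difference of 2 double bonds, showed higher cholesterol genes and lower hypertrophy-associated genes and cell death regulators. G0s2 was 4.95-fold higher with linoleate (log2 2.31, 95% interval 1.00 to 3.61, n = 7 and 8, adjusted p = 0.0289), Angptl4 3.52-fold (1.81, 1.33 to 2.30; the other kept probe 0.24), Pik3ip1 3.48-fold (1.80, 1.11 to 2.48) and Cspg4 3.35-fold (1.74, 1.10 to 2.38). LOC501211 was 5.27-fold lower (-2.40, -3.19 to -1.61), Sgk1 5.12-fold (-2.36, -3.08 to -1.63), Nppb 4.64-fold (-2.21, -3.18 to -1.25) and Hamp 4.45-fold (-2.15, -2.78 to -1.53). All lay on the same side of the stearate mean on 7 of 7 linoleate arrays, except Nppb on 6. Of the 8 stearate arrays Angptl4 and Pik3ip1 were detected on 4 and Cspg4 on 2, and of the 7 linoleate arrays Sgk1 on 4. Cholesterol genes were higher at 8 of 18, 13 over the list alone (camera adjusted p = 4.22e-11), with Hmgcs1 at 2.85-fold and Acat2 at 2.22-fold. Both were higher on 6 of 7 linoleate arrays, and Acat2 was detected on 7 of 8 stearate arrays. Hypertrophy-associated genes were lower at 5 of 15, with 10 lower and 1 higher over the list alone (1.41e-09), with Ccn2 at -1.33 ± 0.20. Cell death regulators were lower at 5 of 18, also 5 over the list alone (0.00255), with Gadd45b at -1.29 ± 0.17. These 3 lists were also called with an estimated correlation, at adjusted p = 0.0038, 0.000373 and 0.0336. With the preset correlation only, PPAR target genes were higher at 3 of 19, with 5 and 1 lower over the list alone (0.011, and 0.224 with an estimated correlation), with Cpt1b at 1.74-fold. Endoplasmic reticulum stress genes were lower at 3 of 22, 4 over the list alone (3.45e-05, and 0.269), with Ddit3 at -1.48 ± 0.30. Amino acid response genes were lower at 3 of 23, with 7 lower and 1 higher over the list alone (2.98e-07, and 0.0817). Oxidative phosphorylation lay lower with 0 of 38 (0.00083, and 0.446) and sarcomere with 2 of 22 (0.0384, and 0.436), with 0 and 2 over the list alone.

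Linoleate and stearate differed at 300 probes, 191 higher and 109 lower with linoleate, 133 of them by at least 2-fold. Without stearate array 4 the count was 462, within numbers 1 to 4 it was 5 and within 5 to 8 it was 752. Without a filter the adjusted p of G0s2 was 0.0947 (0.000272 to 0.149 over alternatives).

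Of the 190 list tests 84 were called with the preset correlation and 35 with an estimated one. The circadian clock, fatty acid synthesis and fibroblast lists were called in no comparison, nor were the other tests of lists not given above. Other cell types were represented by few measured genes, and of these lists only the fibroblast markers had enough members to be tested.

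Of 18 fibroblast markers 9 were measured. Sparc, a matrix protein, was 3.91-fold higher with palmitate than with octanoate (log2 1.97 ± 0.48, adjusted p = 0.0135, higher on 8 of 8 arrays and detected on 6 of 8 octanoate arrays). Dcn, a collagen-binding proteoglycan, was lower with stearate than with control (-1.14 ± 0.40, adjusted p = 0.047, lower on 7 of 8 arrays), but this call was lost without control array 1, 2, 3 or 4 (0.0769, 0.0965, 0.0865 and 0.137) and with array brightness in the fit (0.116), and array weights took the difference to -0.241 (0.688; 0.000701 to 0.688 over alternatives). Of 11 smooth muscle and pericyte markers only Smtn and Cspg4 were measured. Smtn was lower with octanoate and palmitate (above) and with stearate (-1.49 ± 0.33, adjusted p = 0.00198, detected on 4 of 8 stearate arrays). Cspg4 was lower with palmitate (-1.02, adjusted p = 0.0297), lower again with stearate than with palmitate (-1.10, adjusted p = 0.03, on 7 of 8 arrays) and higher with oleate than with stearate (1.80, adjusted p = 0.000105, on 8 of 8 arrays). The palmitate call of Cspg4 was lost without control array 2, 4 or 7 (0.0764, 0.122 and 0.0579; 0.00597 to 0.29 over alternatives). That of stearate against palmitate was lost with median scaling (-0.539, adjusted p = 0.272) and under other settings (0.0504 to 0.0923 among them; 0.00221 to 0.878 over alternatives).

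Of 18 macrophage and leukocyte markers 2 were measured. Cd68, a lysosomal protein of macrophages, was higher with octanoate (log2 1.22 ± 0.22, adjusted p = 7.54e-05) and with palmitate (0.70 ± 0.22, adjusted p = 0.0326) than with control, where it was detected on 1 of 7 arrays. The palmitate call was lost without control array 1, 2, 5 or 7 (0.0555, 0.0624, 0.0711 and 0.0622; 0.00241 to 0.322 over alternatives). Of 15 endothelial markers 1 was measured, Cldn5, called higher with stearate (0.62, adjusted p = 0.0474) while detected on 1 of 8 stearate arrays. Without stearate array 4 it differed by 0.334 (0.102), and its call was lost without control array 1, 2, 3, 4, 5, 6 or 7 (0.0579, 0.0744, 0.059, 0.0634, 0.0677, 0.0874 and 0.0639; 0.0215 to 0.403 over alternatives). Of 6 erythroid markers 4 were measured, with Slc4a1 higher with stearate (0.61, adjusted p = 0.0458, detected on 2 of 8 arrays). This call was lost without control array 1, 2, 4, 6 or 7 (0.0523, 0.0901, 0.0942, 0.0672 and 0.0633) and with array brightness in the fit (0.266, adjusted p = 0.255; 0.0241 to 0.48 over alternatives). None of the 8 adipocyte markers passed the filter.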

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

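The tests of stearate array 4 and of the arrays numbered 4 were chosen after those arrays had been seen, and the pattern of numbers 1 to 4 against 5 to 8 was itself found in the data. The splits of the arrays were planned.

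In 371 groups of values, 353 of gene levels and 18 of array measures, the gap between an extreme array and its nearest neighbour was set against the whole range of its group. It exceeded Dixon's 95% value in 34, where chance alone gives about 1 in 20, or 18.6. Stearate array 4 accounted for 18 of them. It had the lowest level in its group for Atf3 (ratio of gap to range 0.787), Lipe (0.768), Plin2 (0.743), LOC501211 (0.715), Gadd45b (0.696), Pdk4 (0.682), Ddit3 (0.659), Pik3c2g (0.65), Ccn1 (0.583), Egr1 (0.569), Ppp1r15a (0.567), Otud1 (0.547), Rcan1 (0.54) and Por (0.535). It had the highest level for Lpcat1 (0.638), Cspg4 (0.632), Cldn5 (0.627) and Cx3cl1 (0.573). Oleate array 4 was lowest for Lpcat1 (0.594), Ucp3 (0.579) and Ech1 (0.563) and highest for Ppp1r15a (0.787). Linoleate array 4 was lowest for Angptl4 (0.722) and Rnase1 (0.62) and highest for Por (0.677). Palmitate array 4 was lowest for Mlycd (0.681) and Rnase1 (0.569), and octanoate array 4 for Asns (0.533). The highest of their groups were palmitate array 1 for Slc25a29 (0.63), palmitate array 2 for Smtn (0.548), control array 4 for Angptl4 (0.603), control array 2 for Gcgr (0.633) and control array 1 for Lpl (0.672). Octanoate array 2 had a 95th percentile signal of 4510, the nearest other octanoate array 2465 (0.609).

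Stearate array 4 lay near the control level of Pdk4, Acot1 and Plin2, but with the other stearate arrays for Aqp7 (9.361, controls at most 7.547), Sgk1 (10.3, at most 8.084), Hamp (11.91, at most 10.87) and Cdo1 (7.397, at least 8.494). A culture without fatty acid is argued against by the mean of its PPAR target genes, 8.99 (control arrays 8.21 to 8.45); that it lay nearer stearate at 34.3% of 1244 probes called between the other stearate arrays and control decides nothing, as control arrays left out in turn gave 13.4% to 33.5%, and against the exclusion stands that its nearest array over all probes was control array 3 (correlation 0.9755), as for no other array with a fatty acid. An octanoate array is argued against by 48.2% of 1908 such probes (octanoate arrays 12% to 29.1%), but oleate (33.8%; its arrays 7.09% to 59.5%) and linoleate (27.8%; 6.41% to 59.7%) had shares as high, and palmitate (41.1%; 11.8% to 36.5%) nearly, so such an array stays open, though Pdk4, which defined the pattern, was below all of theirs (7.478, at least 9.744). A dim array or poor RNA is argued against by its 95th percentile signal of 3125 (other stearate arrays 664 to 2855) and by 32.1% of probes detected (13.7% to 30.6%). A response weaker in some genes only and a sample from outside the series stay open, and no biological explanation was tested.

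The arrays numbered 4 of octanoate, palmitate, oleate and linoleate deviated alike from their group means, with correlations across probes of 0.674 to 0.95. Octanoate RNA under other labels would have brought the octanoate level of the PPAR target genes. The mean of these genes on the palmitate, oleate and linoleate arrays was 9.33 at the lowest, and 8.53 on the highest octanoate array, which argues against that explanation. One cell preparation behind every array numbered 4 is argued against by control array 4, whose deviations correlated with theirs at -0.369 at the highest, and by stearate array 4, at 0.476 at the highest. A preparation shared by the 4 arrays alone may account for the likeness and was not tested.

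Within groups 4424 probes differed between numbers 1 to 4 and 5 to 8, and 2823 with brightness in the fit (at most 3 in random divisions), arguing against brightness as the whole cause. The median fibroblast marker was Postn, lower in numbers 5 to 8 by log2 -0.691. It lay near background (mean level 6.23), as did Lum (6.3) and Dpt (6.45). Of brighter markers Dcn (-1.15, 10.9), Vim (-0.81, 9.63) and Sparc (-0.87, 8.9) were lower. Ddr2 was higher (0.70, 8.66) and Col1a2 at 0.44 (9.11). As a list the markers were called by fry, not camera (adjusted p = 0.129). With the mean of these markers in the fit 4380 probes differed (at most 50 in random divisions). Dim markers and Ddr2 enter that mean, so it decides nothing. The test was added after the markers were seen and before its result. Heart muscle cells may express some markers too. More fibroblast RNA in numbers 1 to 4 and a shared day or preparation stay open.

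Chance division of the arrays was tested with 100 splits per comparison, the real one included. For octanoate against control 1 split gave as many calls (real 1774, highest other 701), for palmitate 2 (801, 1080), for stearate 1 (993, 834), for oleate 2 (42, 752) and for linoleate 2 (34, 1846). Palmitate against octanoate gave 1 (159, 85), stearate against palmitate 1 (293, 134) and oleate against stearate 3 (509, 2115). Linoleate against stearate gave 4 (300, 1442) and the F test 1 (2102, 344). At most 4 in 100 splits reached each of these counts, uncorrected for multiple tests. For linoleate against oleate, all 100 splits reach its 0 calls by construction (highest other 946), so the count decides nothing. Splits ignored the number sets, and those with several times the real count point to a structure of the arrays, of open cause. Only 1 to 11 other splits called any probe. The correlation of calls with imbalance in numbers 1 to 4 (-0.023 to 0.33) thus decides nothing. Of the highest splits, that for linoleate against control put 6 of 7 and 2 of 7 arrays numbered 1 to 4 on its sides, for oleate against stearate 6 of 8 and 2 of 8, for linoleate against stearate and against oleate 2 of 7 and 6 of 8, for oleate against control 5 of 8 and 3 of 7, and for palmitate against control 3 of 8 and 5 of 7.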

How the results depend on the processing

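Array brightness, the number sets, the pairs and the arrays left out other than single controls were settings chosen after the data were seen. No call of a named gene changed direction under any setting, and of 254 named genes and comparisons 29 lost a call under a setting fixed beforehand other than leaving out a control, and 16 without 1 control array. Most losses came within numbers 1 to 4 (142) or 5 to 8 (30), where groups hold at most 4 arrays, and with control arrays 2 and 4 left out (26). With quantile normalization alone, normexp with offset 50, the authors' processed values or median scaling, each count of called probes stayed within 1.5 times its value above. Weak signal limits the dimmer genes: the 7312 kept probes include many detected on only some arrays, and the filter moved counts. Unless a clause says otherwise, the cause of a change was not tested. The slide as a block could not be run, as the files used here name no slides.

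Counts of called probes follow in the order octanoate, palmitate, stearate, oleate and linoleate against control, then palmitate against octanoate, stearate against palmitate, oleate against stearate, linoleate against oleate and linoleate against stearate, then the F test; comparisons left out stayed within 1.5 times. An adjusted p under 0.01 gave 1058, 361, 397, 26 and 20, then 81, 87, 245 and 140, and 1315, as a stricter threshold must. Probes detected on all arrays, fewer by construction, gave 873, 454, 204, 19 and 13, then 103, 121, 143 and 89, and 915. Without a filter stearate against palmitate gave 167 and linoleate against stearate 197. Array weights gave palmitate 1350, stearate 1650, oleate 89 and linoleate 60, then 540, 860, 1478, 1 and 784, and 3337. With only the 2 groups compared in the fit, and so fewer arrays, oleate gave 23 and linoleate 17, stearate against palmitate 177, oleate against stearate 273 and linoleate against stearate 135. Leaving out 1 control array gave 1425 to 1842 for octanoate, 534 to 941 for palmitate, 668 to 1022 for stearate, 30 to 38 for oleate and 26 to 38 for linoleate.

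With the replicate block, palmitate gave 1666, stearate 1556, oleate 74 and linoleate 61, then palmitate against octanoate 409, stearate against palmitate 810, oleate against stearate 1008 and linoleate against stearate 637, and the F test 3324. Arrays share only a number: deviations of same-numbered arrays correlated at a median of 0.376 and at -0.625 at the lowest of 111 pairs, and 26 of 46 arrays correlated best with an array of their own number, a hint from the data and not from the design. The block ended 3 list calls and made 4, and 2 named genes gained a call, Idi1 with linoleate and Gcgr with oleate.

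With the number sets 1 to 4 and 5 to 8 as a block, palmitate against octanoate gave 263, stearate against palmitate 505, oleate against stearate 786 and linoleate against stearate 451. Within numbers 1 to 4 the counts were 373, 67, 94, 23 and 10, then 16, 1, 8 and 5, and 123. Within 5 to 8 palmitate gave 516, stearate 1783 and linoleate 14, then 282, 1149, 990 and linoleate against stearate 752. With array brightness as a covariate octanoate gave 2736, palmitate 1488 and palmitate against octanoate 239. Without stearate array 4 linoleate against stearate gave 462. Without the 4 number-4 arrays of octanoate, palmitate, oleate and linoleate, palmitate against octanoate gave 334, oleate against stearate 883 and linoleate against stearate 560. Without control arrays 2 and 4 palmitate gave 392, stearate 470 and linoleate 19. Without all 7 of these arrays palmitate gave 456, then palmitate against octanoate 387, stearate against palmitate 455, oleate against stearate 1099, linoleate against oleate 1 and linoleate against stearate 769.

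The correlation of the log2 differences from control fell with the controls split into 3 and 4 arrays, by the construction of that setting. It was 0.627 for octanoate and palmitate, 0.368 for octanoate and stearate, 0.488 for palmitate and stearate, 0.286 for palmitate and oleate, 0.388 for palmitate and linoleate, 0.201 for stearate and oleate, 0.316 for stearate and linoleate and 0.354 for oleate and linoleate. Within numbers 1 to 4 it was 0.738 for octanoate and stearate, 0.709 for octanoate and oleate, 0.81 for palmitate and stearate and 0.734 for stearate and oleate. With the 7 arrays left out octanoate and palmitate gave 0.751.

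Of the 84 list calls 35 were kept with an estimated correlation, and 49 were lost. With fry, 27 calls were lost and 3 made. The remaining settings ended between 0 and 17 list calls each and made between 1 and 11. Direction changed in 2 list tests. Fibroblast markers with linoleate against control were called higher with array weights (adjusted p = 0.0321, and lower at 0.91 without). Endoplasmic reticulum stress with oleate against control, called lower at 0.0447, was higher within numbers 1 to 4 (adjusted p = 0.972).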

Other observations

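The gene here and the lists between number sets were chosen after the data were seen, and no test of an explanation was run on them.

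Besides the genes named above, Nudt7, a peroxisomal enzyme that hydrolyses coenzyme A, was among the probes higher with 4 of the 5 fatty acids. It was higher than control by log2 2.65 ± 0.38 with palmitate (SE, limma adjusted p = 3.57e-06), 2.17 ± 0.38 with stearate (0.000104), 2.55 ± 0.38 with oleate (1.19e-05) and 2.33 ± 0.39 with linoleate (0.000248), and differed by -0.29 ± 0.38 with octanoate (0.607). It was detected on 4 of 7 control arrays and 5 of 8 octanoate arrays. Its calls held under every alternative that kept the probe.

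Between the number sets within groups, oxidative phosphorylation genes were lower in numbers 5 to 8 with a median of log2 -0.33 (camera adjusted p = 0.00163, and 0.828 with an estimated correlation). The other 18 lists tested between these sets were not called, the lowest adjusted p being 0.0672 for amino acid response genes (median 0.23).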
